A study of Mus musculus with 12 samples.

How the data were processed

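Per the labels, RNA of sorted cones from 12 samples was extracted with the PicoPure kit, labelled with biotin by the Affymetrix whole-transcript protocol and hybridised to 1 array per sample. The labels give 8 ug of total RNA for the labelling although each array came from 300 or 500 sorted cells, and whether the RNA was amplified is not given in the sources used here. Any amplification from these unequal numbers of cells cannot be told apart from the construct. The deposited table holds 1 linear intensity per probe and array for 34760 probes, and per the submitters' processing notes RMA and affy were used, with no version given in the sources used here. RMA corrects the background, normalizes between arrays and summarises probes. Which arrays were normalized together is not given in the sources used here. The lowest intensity was 1.7 and the highest 10242.1. No background or detection value was used here, so whether a dim probe stands above background is unknown, and log2 differences of such probes are likely to understate changes. Values were put on the log2 scale with no pseudocount.

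The 8 EGFP columns held 34729 values and the 4 eNpHR-EYFP columns 34760. From line 13588 of the table the EGFP values stood beside the wrong probes, by 2 to 31 lines, as shown by the correlation between the EGFP and eNpHR-EYFP arrays. This shift was found after the data were seen and was repaired. The EGFP mean profile was aligned to the eNpHR-EYFP mean profile by a forward-backward algorithm in which lines can only be lost. It used a t distribution with 3 degrees of freedom and a scale of 0.25 on the log2 scale, a probability of 0.001 per lost line and a posterior of at least 0.999. In all 21142 lines (60.9%) were moved, 114 were left out as ambiguous and 34615 probes were tested, of which 13584 had stood in place. The median correlation between EGFP and eNpHR-EYFP arrays was 0.421 as deposited and 0.944 after the repair, against 0.968 among EGFP arrays, 0.965 among eNpHR-EYFP arrays and 0.934 over the lines in place. Across 251 pairs of probes of the same gene, 1 in place and 1 moved, the correlation of their mean EGFP log2 levels was -0.0185 as deposited and 0.372 after the repair. These values run across genes, which are not independent replicates. In a test, 31 lines were removed at random from the mean of 2 eNpHR-EYFP arrays, which was aligned to the mean of the other 2. There 100% of the kept lines were right and 0.377% were left out. Both sides were of 1 group, so the test does not give the accuracy of the repair between EGFP and eNpHR-EYFP arrays. The alignment uses the similarity of both sets of arrays, and the unequal number of values leaves open that they were processed apart.

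Probes were named from the platform annotation given with the table, in which 21640 probes name 1 gene, 1321 several and 11799 none. Of the first, 21553 matched a gene of the RefSeq annotation of GRCm38.p6 and 0 symbols changed. Probes with several genes name none here. A gene was represented by its brightest probe on average over all arrays, which gave 19902 genes. The array's genome build is not given in the sources used here, so no coordinates are printed.

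Groups were compared with limma 3.58.1 in R 4.3.3, with 1 model of 3 groups and a shared estimate of the spread over all 12 arrays, no filter on low values and no covariate. Contrasts were 220 minus 110 days in EGFP cones, eNpHR-EYFP minus the mean of both EGFP ages, and eNpHR-EYFP minus each EGFP age. Benjamini-Hochberg adjustment ran over all tested probes with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 for lists of at least 5 measured genes, and again with the correlation estimated. The design, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The 34 lists held 910 entries, of which 818 were matched, directly or by a former symbol of 1 current gene; that matching was corrected once after values had been seen. Red blood cell genes had 3 measured members and were not tested.

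Genes named in the text are the 12 largest rises and 12 largest falls that passed with all eNpHR-EYFP arrays on one side of all EGFP arrays, or the 5 lowest p in each direction where none passed. Added are up to 4 members with the smallest p in each list with a call or a called member, of which the text gives some, and a fixed set of cone, rod and glia genes. Predicted genes, clones, olfactory and vomeronasal receptors, small non-coding RNAs and pseudogenes were left out. Rnu12, a small nuclear RNA, was left out under these words after its value was seen.

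The alternatives were fits of the compared groups alone, a trended and robust variance prior, a filter at the median level, quantile normalization, median centring, array weights, the replicate number as a block, probes that name 1 gene, the mean of a gene's probes, and leaving out each array. After the data were seen, fits were added on the lines in place, on the table without repair, without the 3 EGFP arrays lowest in Arr3, and with the mean of the cone list as a covariate. Quantile normalization moved the median of all probes to 0.0002 and centring to 0.04 on the log2 scale in the construct comparison, against 0.05 without them. In data simulated at the spread of these arrays, limma called 86% of 2-fold and 94% of 4-fold changes in the age comparison with 8 false calls, and 91% and 97% in the construct comparison with 7, over 34615 probes with 200 changed. Camera called a list raised by 0.5 in simulated data and 0 other lists. Noise in those data was independent between genes, while the correlation estimated for the oxidative phosphorylation list was 0.251. The simulation therefore says nothing about false calls of lists whose genes correlate. No pair of arrays was identical. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used besides R.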

Results

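Gene expression was measured on 12 Affymetrix mouse arrays, each hybridised with RNA from cones sorted by fluorescence from retinas of C3H/HeNCrl mice. These mice carry the Pde6b rd1 mutation, under which rods die early and cones lose their light response and degenerate later. An adeno-associated virus injected under the retina in young animals carried a fluorescent protein behind the promoter of mouse cone arrestin. In 8 of the arrays the protein was EGFP, the control, with 4 arrays at 110 days of age and 4 at 220 days, each from 500 sorted cells. In the other 4 arrays it was eNpHR-EYFP, a light-driven chloride pump fused to a yellow fluorescent protein, at 165 days and from 300 sorted cells. The arrays are described as biological replicates. The median probe intensity was 6.6 to 7.1 on every array, a log2 level of 2.72 to 2.83, and the 95th percentile was 114 to 134 on the EGFP arrays and 173 to 185 on the eNpHR-EYFP arrays. The number of arrays, 4 per group, limits the precision of every value given here.

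The first comparison asked which transcripts differed between 110 and 220 days in the cells sorted by EGFP. No probe passed, so the age groups are described by values alone. The genes nearest to the threshold on the higher side at 220 days were Wfdc1, Kcng4, Nedd4, Isl1 and Htr3a. Which cells of the sorts these transcripts came from was not tested. Isl1, a homeobox transcription factor of bipolar and ganglion cells, stood at a log2 level of 5.64 ± 0.38 at 110 days and 7.35 ± 0.65 at 220 days (SD, n = 4 each), and Htr3a, a serotonin receptor channel subunit, at 3.21 ± 0.13 and 4.72 ± 0.69. None of the 20 cone phototransduction genes passed, also when adjusted over that list alone.

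Wfdc1 (probe 10575917) had a log2 difference of 1.22 ± 0.15 (SE, n = 4 against 4) and the smallest adjusted p of any probe, 0.0973 by limma with Benjamini-Hochberg adjustment. Kcng4, a modulatory potassium channel subunit, differed by 1.51 ± 0.21, Nedd4, a ubiquitin ligase, by 0.78 ± 0.14, Isl1 by 1.71 ± 0.30 and Htr3a by 1.51 ± 0.27. On the lower side at 220 days stood Trdn with -0.80 ± 0.14, Ppm1j with -1.30 ± 0.28, Hmga2 with -0.37 ± 0.08, the muscarinic receptor gene Chrm3 with -0.60 ± 0.13 and Wfdc6a with -0.59 ± 0.13. Trdn is read by 19 probes, of which the brightest is given, and their mean differed by -0.24 (adjusted p = 0.677). The adjusted p of these 10 genes lay between 0.0973 and 0.498. By limma, 0 of 34615 probes passed after adjustment, and 2331 had an unadjusted p under 0.05. The age groups did not overlap at 462 genes higher and 308 lower at 220 days, 3.87% of 19902 genes, where chance gives 2.86%.

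All 34 gene lists had 0 members past the threshold over all probes. Adjusted over the list alone, 5 bipolar cell genes were higher and 1 lower at 220 days, 1 amacrine cell gene was higher and 1 microglia gene lower. Across 33 lists, camera with a preset correlation called 5, and 0 with an estimated correlation. Amacrine cell genes lay higher at 220 days than other genes (median log2 difference 0.16, adjusted p = 0.00147, and 0.901 with an estimated correlation). Among them were Gad2, which makes the transmitter GABA (1.18 ± 0.26), the calcium-binding protein gene Calb2 (0.86 ± 0.28) and the transcription factor gene Tfap2b, at levels of 4.58 and 5.58. Without replicate 1 of 220 days Calb2 differed by 0.55. Without the 3 EGFP arrays lowest in Arr3 the amacrine median was 0.54, and over the 8 EGFP arrays the mean of this list had a Pearson r of -0.563 with the cone list mean (exact permutation p = 0.147, adjusted p = 0.196, and r = -0.923 without the 2 farthest arrays). Proteasome genes also lay higher (median 0.17, adjusted p = 0.0134, and 0.901 with an estimated correlation), for example Psma4 with 0.45 ± 0.16 and Psmc5 with 0.30 ± 0.12. The proteasome call ended after quantile normalization (0.257) and with a filter on low values (0.188), and without the 3 EGFP arrays lowest in Arr3 the test turned lower, uncalled (median 0.02, adjusted p = 0.646), with Psma4 at 0.13.

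Genes of interferon response and antigen presentation lay lower at 220 days than other genes (median log2 difference -0.15, camera adjusted p = 0.00976, and 0.901 with an estimated correlation). Without the 3 EGFP arrays lowest in Arr3 they turned higher, uncalled (median 0.05, adjusted p = 0.751). Those arrays were chosen by a cone gene, so no call or turn in this setting, for this list or another, says anything about age. Tap2, a peptide transporter for antigen presentation, differed by -0.43 ± 0.17 and B2m, the light chain of MHC class I, by -1.45 ± 0.76. Without replicate 1 of 110 days these were -0.26 and -0.86, and without the 3 arrays -0.21 and -0.46. Microglia and macrophage genes lay lower (median -0.07, adjusted p = 0.0319, and 0.411 with an estimated correlation), led by H2-Aa, an MHC class II chain, with -0.55 ± 0.14, while the median was -0.04 after median centring and, with H2-Aa at -0.30, without the 3 arrays. Cytosolic ribosomal protein genes lay lower (median -0.09, adjusted p = 0.0138, and 0.901 with an estimated correlation), such as Rpl36 with -0.34 ± 0.13 and Rps19 with -0.35 ± 0.17, which was -0.22 without replicate 2 of 110 days or 3 of 220 days. Their median was -0.21 without the 3 arrays and -0.06 after median centring. The 28 other lists tested had adjusted p from 0.0661 for autophagy and lysosome to 0.984 for cell death. In 7 of these lists the median, the mean and the test did not share a sign. Some were called without 1 array or in another setting: Müller glia with the block (0.0277) and without replicate 1 of 110 days (0.00288) or 2 of 220 days (0.0484), bipolar cells without replicate 2 of 220 days (0.0484), cone genes without replicate 3 of 110 days (0.00212), oxidative phosphorylation without replicate 2 of 110 days (0.00343), and autophagy without replicates 2 (0.0181) or 3 (0.0394) of 110 days or 3 of 220 days (0.016) and with the mean of a gene's probes (0.0402).

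Single arrays decided 4 of the 5 list calls between the ages, while the amacrine cell call held without each array in turn (highest adjusted p 0.0435). The interferon call ended without replicate 1 (0.288) or replicate 4 (0.0882) of 110 days, the 2 arrays whose mean over that list was 4.0 and 3.7 against 3.2 to 3.3 on the other EGFP arrays. The proteasome call ended without replicate 4 of 110 days (0.522) or replicate 1 of 220 days (0.286). The microglia call ended after quantile normalization (0.0708), with a filter on low values (0.232), without the 3 EGFP arrays lowest in Arr3 (0.359), and without replicate 1 (0.0776) or 4 (0.102) of 110 days, or replicate 1 (0.0862) or 2 (0.0664) of 220 days. The ribosomal call ended without replicate 2 (0.585) or 3 (0.118) of 110 days, or replicate 2 (0.0926) or 4 (0.103) of 220 days. On the lines of the table that had stood in place the amacrine, proteasome and ribosomal calls ended (each 0.404), and the microglia and interferon lists could not be tested. Over all alternatives the camera adjusted p ran from 5.53e-06 to 0.901 for amacrine cells, 0.00016 to 0.901 for interferon, 0.000459 to 0.901 for proteasome, 0.0238 to 0.411 for microglia and 2.73e-09 to 0.901 for ribosomal genes.

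The cone phototransduction list had a median log2 difference of 0.28 from 110 to 220 days, with an adjusted p of 0.373 by camera. It turned without the 3 EGFP arrays lowest in Arr3, with a median of -0.49 and a call as lower (0.0308, range 0.00212 to 0.942), but Arr3 is on this list and 2 of the 3 arrays were from 110 days, so their removal raised the cone mean at 110 days by the choice itself and the turn says nothing about age. Arr3, the cone arrestin gene, stood at 7.11 ± 2.54 at 110 days and 7.93 ± 0.81 at 220 days (SD, n = 4 each), and the 95% confidence interval of its difference ran from -1.4 to 3.0. The short-wave opsin gene Opn1sw stood at 5.89 ± 2.71 and 7.12 ± 0.56, the medium-wave opsin gene Opn1mw at 7.86 ± 2.02 and 8.26 ± 0.89, and the cone transducin gene Gnat2 at 8.61 ± 0.96 and 8.48 ± 0.57. The sign of these 4 differences was not fixed, with ranges over the alternatives of -0.95 to 1.66 for Arr3, -0.88 to 2.05 for Opn1sw, -0.89 to 1.13 for Opn1mw and -0.66 to 0.23 for Gnat2. The 110-day arrays differed most among themselves, with Arr3 at 4.58 and 5.29 on replicates 1 and 4 and at 8.92 and 9.64 on replicates 2 and 3.

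**Figure D1:**
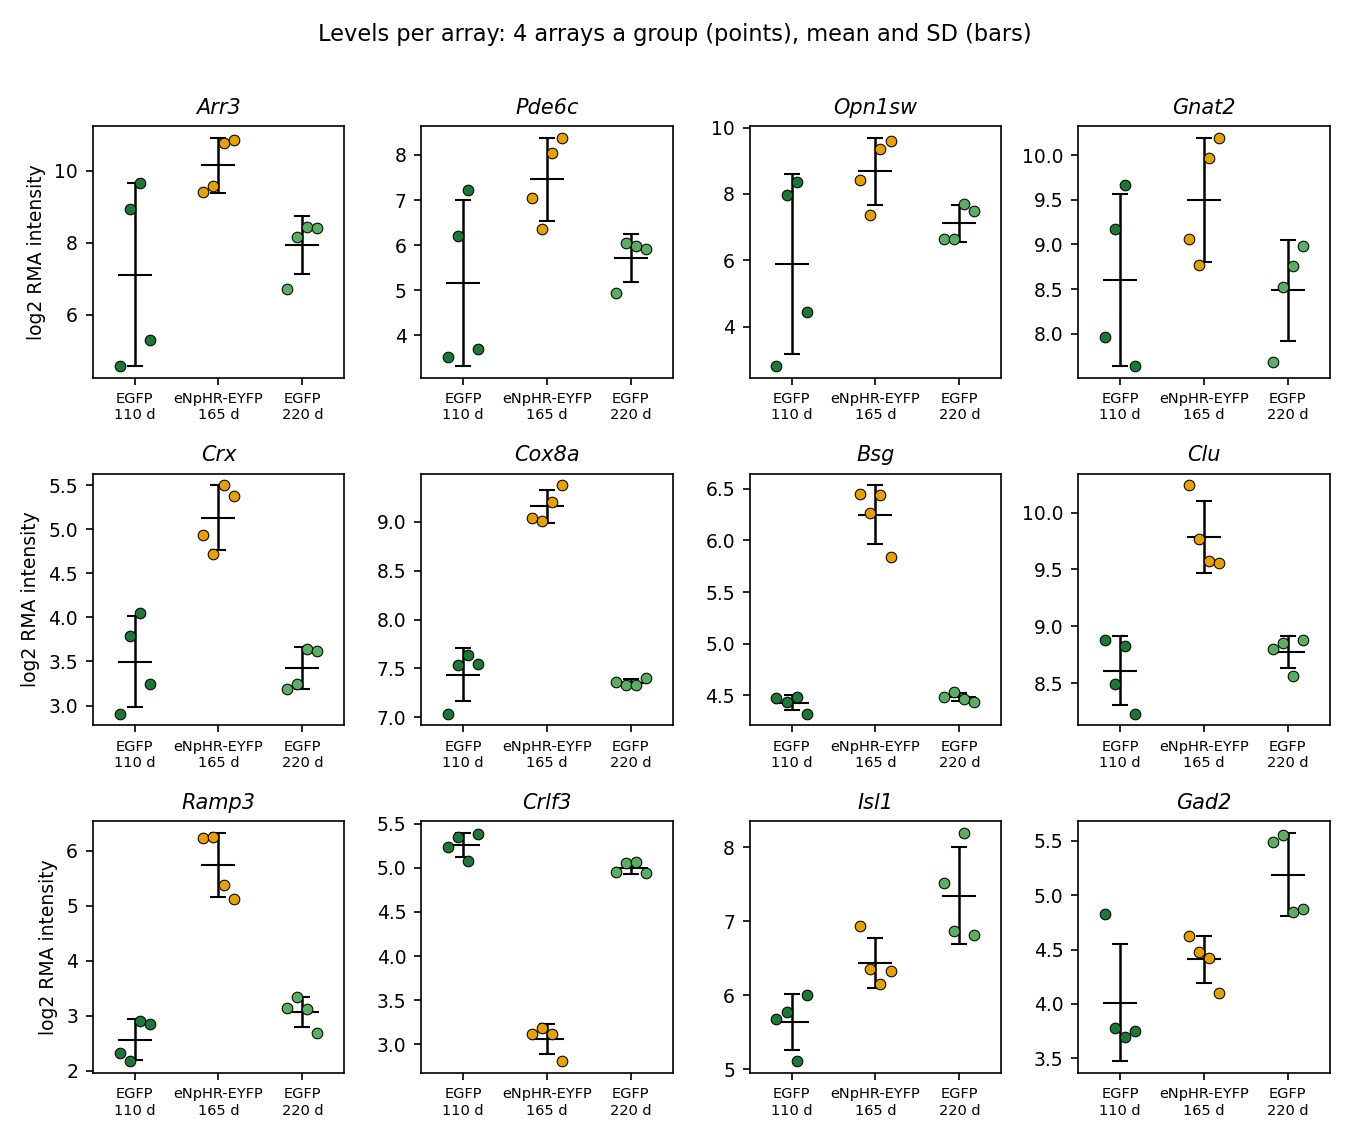
Log2 intensity of 12 genes on each array (points, 4 per group), with the group mean and SD (bars), for EGFP at 110 days, eNpHR-EYFP at 165 days and EGFP at 220 days. Ramp3, Cox8a, Bsg, Clu and Crx were higher and Crlf3 lower on all 4 eNpHR-EYFP arrays than on all 8 EGFP arrays, while Arr3 spread from 4.58 to 9.64 on the EGFP arrays.

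The next comparison set the eNpHR-EYFP cones at 165 days against the mean of both EGFP ages. Genes of oxidative phosphorylation, which makes ATP in mitochondria, were higher in eNpHR-EYFP cones in 66 of 73 measured cases and lower in 0, and 23 of 31 proteasome genes were raised and 1 lowered. After quantile normalization these counts were 35 and 1 of 73, and 14 and 4 of 31. The largest single rise was that of Ramp3, a receptor activity-modifying protein, from log2 levels of 2.56 ± 0.37 and 3.07 ± 0.28 in the EGFP groups to 5.75 ± 0.58 (SD, n = 4 each), a 7.64-fold difference. The largest fall among the genes named here was that of the cytokine receptor-like gene Crlf3, from 5.26 ± 0.14 at 110 days and 5.0 ± 0.07 at 220 days to 3.06 ± 0.17. Crx, a transcription factor of photoreceptors, rose 3.18-fold, while the opsin genes did not pass the test. Construct, number of sorted cells and any age course that is not linear cannot be told apart in this comparison.

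By limma with Benjamini-Hochberg adjustment, 9659 of 34615 probes (27.9%) passed, 6456 higher and 3203 lower in eNpHR-EYFP cones, and 1567 of them differed at least 2-fold (1248 higher, 319 lower). The called probes stood for 4715 genes higher and 2104 lower. Of 19902 genes, 2821 were higher and 1223 lower on all 4 eNpHR-EYFP arrays than on all 8 EGFP arrays, 20.3% where chance gives 0.404%. After quantile normalization of the 12 arrays 8482 probes passed, with 4364 higher and 4118 lower, so the share of higher calls was 51.5% in place of 66.8%. The deposited values of EGFP and eNpHR-EYFP arrays differed in scale at the bright end, so counts without this step include that difference.

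After Ramp3 (probe 10374197, log2 difference 2.93 ± 0.24, SE), the largest rises among genes with all eNpHR-EYFP arrays above all EGFP arrays were those of the neuropeptide gene Cck (2.44 ± 0.38), the homeobox gene En2 (2.43 ± 0.48), Yipf1 (2.40 ± 0.18) and S100a1, which encodes a calcium-binding protein (2.31 ± 0.19). Mfge8, a secreted protein that tags dying cells for uptake, rose by 2.29 ± 0.49, Mcts2 by 2.29 ± 0.18, the arrestin gene Sag by 2.25 ± 0.69, the proteasome subunit gene Psmb7 by 2.22 ± 0.21, the calcium-binding protein gene Calb1 by 2.20 ± 0.38, Rida by 2.20 ± 0.25 and Ift22, of intraflagellar transport, by 2.14 ± 0.23. Adjusted p by limma ran from 8.81e-06 for Yipf1 to 0.0297 for Sag. The Sag call ended after quantile normalization (1.82, adjusted p = 0.0719) and without replicate 4 of 110 days (0.0501), replicate 1 of 220 days (0.0517) or replicates 1 (0.052), 3 (0.0822) or 4 (0.0733) of eNpHR-EYFP, within a range of 0.00665 to 0.4 over its alternatives. With the cone list mean as a covariate the difference was 1.15 for En2 (adjusted p = 0.0122), 0.94 for Mfge8 (0.00821) and 0.34 for Sag (0.4), and without the 3 EGFP arrays lowest in Arr3 it was 1.28 for Sag (0.0151).

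Crlf3 fell by 2.07 ± 0.09 on the log2 scale (adjusted p = 8.46e-07 by limma). Josd1, which encodes a deubiquitinating enzyme, fell by 1.99 ± 0.13, Pip by 1.91 ± 0.16, Smim15 by 1.68 ± 0.25 and the cardiac actin gene Actc1 by 1.59 ± 0.19. Serpini1, which encodes neuroserpin, fell by 1.53 ± 0.21, Zfp352 by 1.52 ± 0.25, the X-linked zinc finger gene Zfx by 1.52 ± 0.16, Paxbp1 by 1.52 ± 0.10, the protocadherin gene Pcdhb21 by 1.51 ± 0.13, the neuronal transcription factor gene Neurod4 by 1.48 ± 0.26 and Fignl1 by 1.43 ± 0.17. All 24 genes of these 2 groups lay on one side of all 8 EGFP arrays on each of the 4 eNpHR-EYFP arrays.

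Of 20 cone phototransduction genes, 7 rose and 1 fell in eNpHR-EYFP cones (9 and 1 adjusted over the list alone), with a median log2 difference of 0.87, and 12 did not pass. The list was not called by camera (adjusted p = 0.101), except without replicate 3 of 110 days (0.0175) or replicate 2 of eNpHR-EYFP (0.0429), within a range of 0.0175 to 0.889. After quantile normalization 4 of these genes were higher and 1 lower, and without the 3 EGFP arrays lowest in Arr3 5 were higher and 1 lower, with a median of 0.43. With the cone list mean as a covariate, which contains these genes, 2 were higher and 2 lower (median 0.11). The cone transducin subunit gene Gngt2 rose by 2.01 ± 0.39, the kinase gene Grk1 by 0.78 ± 0.09 and Pdc, which encodes phosducin, by 1.75 ± 0.46, although Pdc did not pass after quantile normalization (1.22, adjusted p = 0.0643, range 0.00479 to 0.0643). Grk1 was dim, at 2.72 to 2.89 at 110 days, near the array medians. Arr3 rose by 2.63 ± 0.86 (limma adjusted p = 0.0407) and the cone phosphodiesterase gene Pde6c by 2.02 ± 0.66 (adjusted p = 0.0409). Of 12 fits without 1 array each, Arr3 passed in 3 and Pde6c in 3. The Arr3 call ended without replicate 4 of 110 days (0.064), without replicates 1 to 4 of 220 days (0.0688, 0.0588, 0.0538 and 0.054) and without replicates 1 to 4 of eNpHR-EYFP (0.0586, 0.0627, 0.107 and 0.0973), and after quantile normalization (0.0861), within a range of 0.0113 to 0.664. The Pde6c call ended without replicates 1 (0.0596) and 4 (0.0631) of 110 days, replicates 1 to 4 of 220 days (0.069, 0.0554, 0.0566 and 0.0581) and replicates 1 (0.0656), 3 and 4 (each 0.11) of eNpHR-EYFP, and after quantile normalization (0.117), within a range of 0.00894 to 0.597. With that covariate the difference was 0.94 for Gngt2 (0.00317), 0.47 for Pdc (0.0604), 0.20 for Arr3 (0.664) and 0.12 for Pde6c (0.597). Without the 3 EGFP arrays lowest in Arr3 it was 1.16 for Pdc (0.0242), 1.34 for Arr3 (0.024) and 1.11 for Pde6c (0.0917). Leaving out arrays chosen by low Arr3 raises the EGFP level of Arr3 and narrows its spread by the choice itself. Values in this setting therefore do not check the construct difference of cone genes. The same holds for the cone list, Sag and the other cone genes without these 3 arrays.

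Other cone genes did not pass: log2 differences were 2.18 ± 0.92 for Opn1sw (adjusted p = 0.099 by limma), 1.52 ± 0.77 for Opn1mw (0.168), 0.95 ± 0.41 for Gnat2 (0.109), 1.73 ± 0.84 for the phosphodiesterase gene Pde6h (0.152), 0.33 ± 0.11 for the channel gene Cnga3 (0.0524) and 0.60 ± 0.25 for Cngb3 (0.0993). With that covariate Opn1sw (-0.35), Opn1mw (-0.62), Gnat2 (-0.17) and Pde6h (-0.68) turned lower, of which Pde6h passed (0.0143), and Cnga3 stood at 0.22 and Cngb3 at 0.15. Without the 3 arrays the differences were 0.97 for Opn1sw, 0.45 for Opn1mw, 0.42 for Gnat2 and 0.53 for Pde6h. Gnat2 stood at 0.43 after quantile normalization, and without replicate 4 of eNpHR-EYFP Cnga3 stood at 0.19 and Cngb3 at 0.28. Without replicate 3 of 110 days Opn1sw (0.0374), Gnat2 (0.0463) and Pde6h (0.0498) passed, and without replicate 2 of eNpHR-EYFP Cngb3 (0.0345) and the rod transducin gene Gnat1 (0.0199) did. Cnga3 passed without replicate 3 of 220 days (0.0466), replicate 1 (0.0411) or 2 (0.0402) of eNpHR-EYFP, after quantile normalization (0.0372) or median centring (0.0426), with a trended and robust prior (0.0445), with probes that name 1 gene (0.0367) and with the mean of a gene's probes (0.0352). It was dim, at 2.10 to 2.35 at 220 days, below the array medians. The rod genes Gnat1 (0.29 ± 0.11), Pde6b (0.13 ± 0.16) and Nrl (-0.04 ± 0.10) did not pass, at group means of 2.18 to 2.80 on the log2 scale, where the array medians were 2.72 to 2.83. Over the alternatives Pde6b ran from -0.04 to 0.23 and Nrl from -0.09 to -0.01. Among 14 rod genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), with Reep6 at 0.91 ± 0.12 and the channel gene Cngb1 at -0.48 ± 0.13. The Cngb1 call ended without replicate 1 of eNpHR-EYFP (adjusted p = 0.0601, range 5.28e-05 to 0.122) and with the cone list mean as a covariate (0.122). Among 15 photoreceptor transcription factors 4 rose and 2 fell (4 and 2 adjusted over the list alone), with Crx at 1.67 ± 0.22 (adjusted p = 0.000233), the retinoid receptor gene Rxrg at 1.64 ± 0.35 and Neurod4 lower. With that covariate the difference was 1.09 for Crx (0.000378) and 0.93 for Rxrg (0.0822). The rod list (adjusted p = 0.951) and the transcription factor list (0.701) were not called by camera. Gapdh was not analysed here.

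Camera with a preset correlation called 4 of 33 lists as higher in eNpHR-EYFP cones, and 0 with an estimated correlation. The called lists were bright, with array means from 5.40 (oxidative stress) to 9.68 (ribosomal), where array medians were 2.72 to 2.83. The chaperone list, at 5.82 to 6.56, was not called. EGFP and eNpHR-EYFP arrays differ in scale at the bright end, and after quantile normalization 1 of the 4 calls was left. Without that step these calls cannot be told apart from scale. Oxidative phosphorylation genes rose in 66 of 73 cases (70 adjusted over the list alone), with a median log2 difference of 0.72 (adjusted p = 3.88e-21, and 0.535 with an estimated correlation). Cox8a, of cytochrome c oxidase, rose by 1.76 ± 0.11, and the complex I subunit genes Ndufa5 by 1.54 ± 0.12, Ndufa3 by 1.29 ± 0.09 and Ndufa10 by 1.04 ± 0.07. Proteasome genes rose in 23 of 31 cases and fell in 1 (25 and 2 adjusted over the list alone), with a median of 0.77 (adjusted p = 2.25e-07, and 0.658 with an estimated correlation). Psmc5 rose by 1.28 ± 0.11, Psmb3 by 1.24 ± 0.09 and Psmd8 by 1.02 ± 0.08. After quantile normalization 35 oxidative phosphorylation genes were higher and 1 lower (median 0.28, adjusted p = 2.58e-05), and 14 proteasome genes higher and 4 lower (median 0.31, adjusted p = 0.118). Quantile normalization left differences of 0.77 for Ndufa3, 0.53 for Ndufa10, 0.76 for Psmc5, 0.76 for Psmb3 and 0.50 for Psmd8, which passed. Over all alternatives adjusted p ran from 2.08e-22 to 0.535 and from 2.26e-08 to 0.658.

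Cytosolic ribosomal protein genes rose in 31 of 55 cases and fell in 2 (33 and 2 adjusted over the list alone), with a median log2 difference of 0.36 (camera adjusted p = 0.00023, and 0.83 with an estimated correlation), but after quantile normalization 8 were higher and 8 lower, the median was -0.03 and the test turned lower (adjusted p = 0.88). Rpl36 rose by 1.43 ± 0.11, Rpl22 by 1.24 ± 0.14 and Fau by 1.06 ± 0.09, and ribosomal protein genes have near-identical copies that probes may share. Oxidative stress response genes rose in 13 of 27 cases and fell in 0 (13 and 0 adjusted over the list alone), with a median of 0.41 (adjusted p = 0.00412, and 0.658 with an estimated correlation). The ferritin gene Fth1 rose by 1.21 ± 0.09, the mitochondrial thioredoxin gene Txn2 by 1.19 ± 0.11 and Keap1, a repressor of the antioxidant response, by 1.18 ± 0.13. After quantile normalization 8 of these genes were higher and 0 lower, with a median of 0.12 (adjusted p = 0.228). With a filter on low values the ribosomal (0.0501) and the oxidative stress call (0.0622) ended, and the latter also on the lines in place (0.376). Quantile normalization left differences of 0.72 for Rpl22, 0.52 for Fau, 0.76 for Fth1 and 0.67 for Txn2, and the mean of a gene's probes 0.60 for Rpl36, which passed. Over all alternatives adjusted p ran from 1.3e-05 to 0.88 for ribosomal genes and from 0.00195 to 0.658 for oxidative stress genes.

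**Figure D2:**
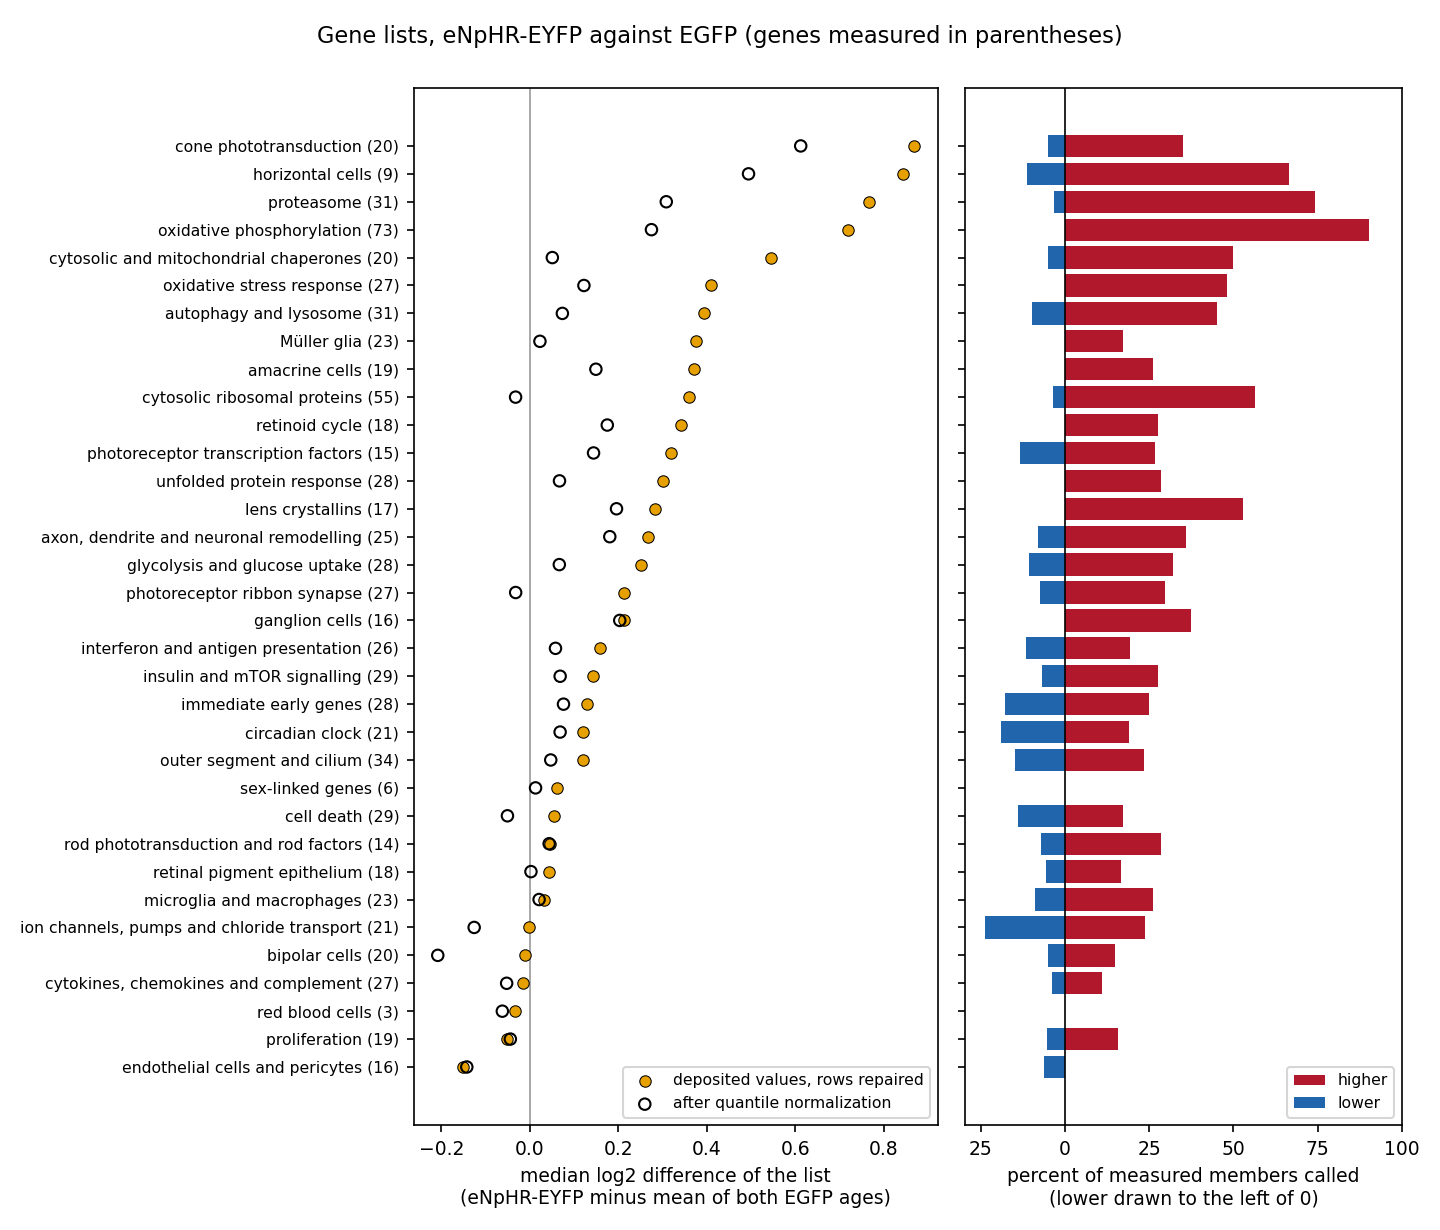
Left, median log2 difference of each gene list, eNpHR-EYFP minus the mean of both EGFP ages, from the repaired values (filled) and after quantile normalization (open); right, percent of measured members called higher or lower. Oxidative phosphorylation had a median of 0.72 and 0.28 after quantile normalization, while that of ribosomal proteins turned from 0.36 to -0.03, and those of ribbon synapse and cell death genes also turned below 0.

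Of 86 markers of 5 other retinal cell types, 23 were higher and 2 lower in the eNpHR-EYFP sorts, and 16 were higher and 7 lower after quantile normalization. Of 23 Müller glia genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; median log2 difference 0.38), among them Clu (1.09 ± 0.15), the intermediate filament gene Vim (1.07 ± 0.19) and Sparcl1 (1.88 ± 0.37), while Rlbp1 (0.88 ± 0.51) and Gfap (-0.02 ± 0.08) did not pass. After quantile normalization Clu stood at 0.60 (adjusted p = 0.0201) and Vim at 0.56 (0.044), while Rlbp1 stood at 0.44, and at 0.41 without replicate 1 of eNpHR-EYFP, and passed with the cone list mean as a covariate (1.93, 0.0189). Gfap ran from -0.08 to 0.03 over its alternatives. Of 9 horizontal cell genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.84), among them Septin4 (1.88 ± 0.16), the connexin gene Gja10 (0.84 ± 0.09) and Calb1. Gja10 was dim, at 1.89 to 2.04 at 220 days, below the array medians. Of 19 amacrine cell genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.37), led by C1ql1 with 1.79 ± 0.24. Of 16 ganglion cell genes 6 rose and 0 fell (7 and 1 adjusted over the list alone; median 0.21), for example Rbpms with 0.78 ± 0.09 and Eomes with 0.74 ± 0.12. Of 20 bipolar cell genes 3 rose and 1 fell (3 and 0 adjusted over the list alone; median -0.01), among them Car8 (1.67 ± 0.23) and Sebox (1.13 ± 0.10). These 5 lists were not called by camera, with adjusted p of 0.806, 0.13, 0.501, 0.571 and 0.92 in this order, except the horizontal cell list without replicate 2 of eNpHR-EYFP (0.0496, range 0.0496 to 0.83). After quantile normalization 3 Müller glia genes were higher and 1 lower, and 3 bipolar cell genes higher and 4 lower, and the medians were 0.02 for Müller glia, 0.49 for horizontal, 0.15 for amacrine and -0.21 for bipolar cells. With the cone list mean as a covariate 10 Müller glia genes were higher and 0 lower (median 0.84), 9 and 0 amacrine (0.76), 3 and 1 ganglion (0.09) and 4 and 0 bipolar cell genes (0.23). Without the 3 arrays the bipolar median was 0.09.

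**Figure D3:**
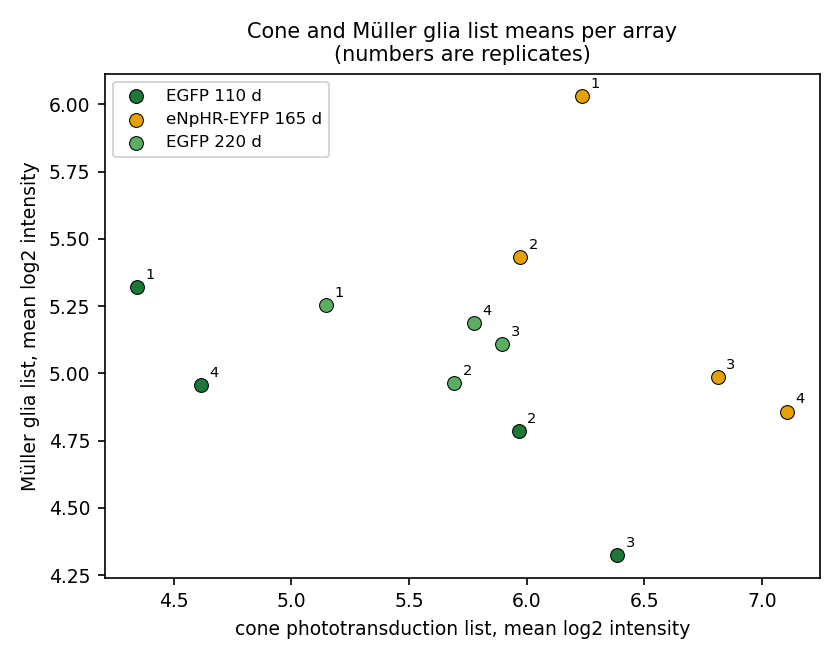
Mean log2 intensity of the 20 cone phototransduction genes (horizontal) and the 23 Müller glia genes (vertical) on each of the 12 arrays, coloured by group and numbered by replicate. The cone mean ran from 4.34 to 6.39 on the EGFP arrays and from 5.97 to 7.11 on the eNpHR-EYFP arrays.

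Each EGFP age was also compared alone with eNpHR-EYFP by limma. Against 110 days, 8150 of 34615 probes passed, 5451 higher and 2699 lower in eNpHR-EYFP cones, with 51.8% higher after quantile normalization in place of 66.9%. Against 220 days, 7263 probes passed, 4996 higher and 2267 lower, with 51.3% higher after quantile normalization in place of 68.8%. Both comparisons use the same 4 eNpHR-EYFP arrays, so their overlap is not given.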

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

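The correlation of the Müller glia list with the cone list was chosen as a test only after the result was seen. In 32 of 486 tests (6.58%), 1 array of a group stood far from the other 3, by a gap of more than 0.829 of the group's range, where chance picks out about 1 in 20 groups. Of these 12 were at 110 days, 13 at 220 days and 7 in eNpHR-EYFP.

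At 220 days replicate 1 was low in cone genes: Arr3 stood at 6.72 against 8.16 to 8.42 on the other arrays, Pde6c at 4.93 against 5.91 to 6.05, Pde6h at 7.21 against 8.70 to 8.99 and Pdc at 6.85 against 7.20 to 7.25. On the same array Stmn3 stood at 6.63 (6.07 to 6.15 on the others), Psmd8 at 7.35 (7.14 to 7.16), Gfap at 2.41 (2.29), Gja10 at 1.89 (2.04) and the mean of the chaperone list at 6.30 (6.04 to 6.08). Replicate 3 held Rps19 at 5.86 (6.35 to 6.42), Mcts2 at 2.98 (3.60 to 3.68) and Cnga3 at 2.35 (2.10 to 2.14), and replicate 4 held Vim at 7.08 (6.42 to 6.46).

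At 110 days replicate 1 held the amacrine genes Gad2 at 4.82 (3.70 to 3.78 on the others) and Tfap2b at 5.39 (4.18 to 4.38), and Cox8a at 7.04 (7.54 to 7.63). Replicate 2 held Trdn at 6.18 (6.49 to 6.52) and Pkm at 7.47 (8.02 to 8.03). Replicate 3 held Actc1 at 4.34 (3.50 to 3.62), Ndufa10 at 6.77 (6.60 to 6.62), Grk1 at 2.89 (2.72) and the clock gene Nr1d1 at 3.14 (3.74 to 3.84). Replicate 4 held Ift88 at 3 (3.43 to 3.47), Cngb1 at 5.06 (4.34 to 4.46) and the mean of the axon and dendrite list at 3.61 (3.70 to 3.71). In eNpHR-EYFP replicate 2 held Psma4 at 7.55 (7.15 to 7.21) and the mean of the sex-linked list at 2.98 (2.70 to 2.73), and replicate 3 held Septin4 at 8.69 (7.81 to 7.88) and Oas1a at 2.81 (3.09 to 3.10). Replicate 4 held Pkm at 8.25 (9.18 to 9.20), Atp1b1 at 3.80 (4.88 to 5.0) and Il18 at 4.39 (4.82 to 4.85).

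Cone gene levels differed among the 8 EGFP arrays, with a cone list mean of 4.34 to 6.39. A difference in scale within the deposited values is argued against, since 99.2% of the SD of that mean was left after quantile normalization. These arrays already had like distributions (95th percentile 114 to 134), so that step could change little. It says nothing about differences present before RMA. Other retinal cells in the sort may contribute: across the 8 arrays the Müller glia list mean had a Pearson r of -0.652 with the cone list mean (exact permutation p = 0.0719, Benjamini-Hochberg adjusted p = 0.144; Spearman -0.69, p = 0.0694, adjusted p = 0.128). The Pearson r was -0.837 without the 2 farthest arrays, -0.916 within 110 days and -0.54 within 220 days, so the test left this open. No biological explanation was tested.

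Of 8 lists related to the cone list in this way, 3 passed: outer segment and cilium (r = 0.961, adjusted p = 0.000298; Spearman 0.976, adjusted p = 0.00159; 0.997 without the 2 farthest arrays, 0.986 and 0.997 within 110 and 220 days), rod (0.942, 0.000298; 0.976, 0.00159; 0.911, 0.998 and 0.836) and ribbon synapse (0.872, 0.0088; 0.905, 0.0122; 0.919, 0.937 and 0.832). Some genes of these lists serve cones as well. The others had r of -0.563 for amacrine cells (-0.923 without the 2 farthest arrays), -0.371 for bipolar cells, 0.511 for ribosomal genes and 0.587 for oxidative phosphorylation, which was -0.195 without the 2 farthest arrays.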

How the results depend on the processing

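The fits on lines in place, without repair, without the 3 EGFP arrays lowest in Arr3 (replicates 1 and 4 of 110 days and replicate 1 of 220 days) and with the cone list mean as a covariate were chosen only after the data were seen. Between 110 and 220 days limma called 0 probes, and 1 with only the groups compared (Lpgat1, adjusted p = 0.0375), 1 with only probes that name 1 gene (Wfdc1, 0.034), Wfdc1 (0.0264) and Kcng4 (0.0417) with the mean of a gene's probes over genes alone, 1 without the 3 arrays lowest in Arr3 (Kcng4, 0.0296), 1 with the covariate (Kcng4, 0.00871) and 0 to 1 without each array, the 1 being C130036L24Rik without replicate 3 of 220 days (0.0253). Lpgat1 and C130036L24Rik were named after their values were seen. Over its alternatives adjusted p ran from 0.0264 to 0.333 for Wfdc1 and from 0.00871 to 0.383 for Kcng4.

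With eNpHR-EYFP 9659 probes were called, 7749 to 9468 without each array, 7649 without the 3 arrays, 6579 with the covariate and 7243 to 10020 under the choices made beforehand. Of these, 7243 was of the 17307 probes past the filter on low values (41.9%), and 7850 of the 21587 that name 1 gene (36.4%). On the lines in place 2517 were called among 13584 probes (18.5% in place of 27.9%), and 20818 without the repair, where EGFP values stand beside wrong probes. Against 110 days these counts were 8150, 2087 and 19803, with 4591 without the 3 arrays, which leaves 2 arrays at 110 days, and 6619 to 8231 without each array. Against 220 days they were 7263, 1743 and 19557, and 5548 to 7054 without each array.

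Camera called 5 lists between the ages: 0 with an estimated correlation, 3 after quantile normalization, 3 with a filter on low values, 0 on the lines in place, where 24 of 33 lists were tested and 2 of the 5 were not, and 8 without the 3 arrays, of which 2 are shared. Without them 13 lists turned direction, and 3 were called as lower that had lain higher uncalled: cone (0.0308, range 0.00212 to 0.942), outer segment (0.00665 to 0.995, lowest without the 3 arrays) and oxidative phosphorylation (7.84e-05 to 0.989, lowest likewise). Müller glia (0.00528), bipolar cells (0.00856, the lowest in a range to 0.901) and unfolded protein response (0.00752, the lowest in a range to 0.901) were called without them too. The arrays were chosen by Arr3, a cone gene, and 2 of the 3 were from 110 days, where they had the lowest cone list means (4.34 and 4.62) and the highest Müller glia means (5.32 and 4.96), so no call or turn in this setting says anything about age. Proteasome turned lower (0.646) and interferon higher (0.751), both uncalled. Without each array it called 2 to 6, with 2 without replicate 4 of 110 days and 3 without replicate 1 of 220 days. With eNpHR-EYFP it called 4: 0 with an estimated correlation, 1 after quantile normalization, 2 with the filter, and 4 to 7 without each array, with 7 without replicate 2 of eNpHR-EYFP. The cause was not tested.

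Of 160 genes named for eNpHR-EYFP 146 passed, 108 of them under every alternative and 133 without each array in turn. Pde6h turned from 1.73, which did not pass, to -0.68 (adjusted p = 0.0143, range 0.0143 to 0.429) with the covariate, which contains Pde6h itself. Over gene and setting pairs 132 lost and 30 gained a call with eNpHR-EYFP, and 0 and 5 between the ages. The replicate numbers did not pair the samples: 2 of 12 pairs with the same number correlated above 0.1, and 5 of 12 arrays correlated best with their own number. With the replicate number as a block 0 probes were called between the ages and 9258, 7735 and 6856 in the other comparisons, and 6 and 4 lists, the sixth being Müller glia (0.0277, range 0.00288 to 0.901). No background measure was used, so what dim signal hides is unknown.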

Other observations

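The tests on markers of other retinal cells and on splits at an unadjusted p were chosen only after the result was seen. The unfolded protein response, chaperone and autophagy lists were not called by camera in eNpHR-EYFP cones. Of 28 unfolded protein response genes 8 rose and 0 fell (9 and 1 adjusted over the list alone; adjusted p = 0.108), with the transcription factor gene Xbp1 at 0.97 ± 0.09, the chaperone gene Calr at 1.12 ± 0.10, Ppp1r15a at 1.28 ± 0.15 and Dnajb9 at 1.40 ± 0.17. Of 20 chaperone genes 10 rose and 1 fell (10 and 1 over the list alone; 0.13), led by Dnajb1 with 1.92 ± 0.11 and Hspe1 with 0.88 ± 0.12, but after quantile normalization 3 were higher and 3 lower. Of 31 autophagy and lysosome genes 14 rose and 3 fell (14 and 4 over the list alone; 0.101), among them Map1lc3a (1.31 ± 0.13), Gabarapl1 (1.24 ± 0.14) and Lamp1 (1.23 ± 0.15), with 9 higher and 5 lower after quantile normalization. Quantile normalization left 5 unfolded protein response genes higher and 2 lower. It left Xbp1 at 0.61 and Hspe1 at 0.38, which passed. Without replicate 2 of eNpHR-EYFP the unfolded protein response list was called (0.0496, range 0.0496 to 0.83), and without replicate 4 the autophagy list (0.0245, range 0.0245 to 0.83).

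Of 28 glycolysis genes 9 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.501), led by Bsg, a partner of lactate transporters, with 1.79 ± 0.11, and Pkm with 0.92 ± 0.19, while 3 were higher and 4 lower after quantile normalization. Of 27 ribbon synapse genes 8 rose and 2 fell (11 and 3 over the list alone; 0.563), with the synaptic vesicle gene Syp at 1.07 ± 0.08 and Snap25 at 1.16 ± 0.12, and 5 higher and 4 lower after quantile normalization, when Snap25 stood at 0.67. Of 34 outer segment and cilium genes 8 rose and 5 fell (9 and 5 over the list alone; 0.934), with Ahi1 at -1.13 ± 0.13 and Ift88 at -0.60 ± 0.10, and 1 higher and 7 lower after quantile normalization. Of 18 retinoid cycle genes 5 rose and 0 fell (7 and 0 over the list alone, camera adjusted p = 0.254), such as Rdh10 with 1.19 ± 0.24. After quantile normalization 2 retinoid cycle genes were higher and 0 lower. Of 21 channel and pump genes 5 rose and 5 fell (8 and 5 over the list alone; 0.894), with the sodium pump gene Atp1b1 at 1.23 ± 0.22 and the potassium channel gene Kcnma1 at -0.84 ± 0.13, and 2 higher and 5 lower after quantile normalization. Kcnma1 stood at -0.53 with the mean of its probes. Clcn3 (0.62 ± 0.10), Rdh14 (0.58 ± 0.11) and Pkm did not pass after quantile normalization (adjusted p = 0.414, 0.524 and 0.146, the highest over their alternatives, where the lowest were 0.000277, 0.000574 and 0.000173).

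Of 29 cell death genes 5 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.889), with Bcl2l1, which inhibits apoptosis, at 1.2 ± 0.12, Bad at 0.71 ± 0.08 and Mcl1 at -0.88 ± 0.13. Of 29 insulin and mTOR genes 8 rose and 2 fell (9 and 4 over the list alone; 0.701), among them Foxo1 (0.87 ± 0.13), Igf1r (0.61 ± 0.10) and Rheb (0.66 ± 0.08), with 5 and 5 after quantile normalization, when Rheb did not pass (0.3, range 5.15e-05 to 0.3). Of 23 microglia genes 6 rose and 2 fell (6 and 2; 0.956), such as Tyrobp with 0.93 ± 0.14 and Csf1r with 0.41 ± 0.09. Of 16 endothelial genes Flt1 alone passed, at -0.77 ± 0.07 (0 and 1; 0.0918). Of 17 lens crystallin genes 9 rose and 0 fell (9 and 1; 0.23), among them Cryba2 (0.78 ± 0.12) and Crybb3 (0.69 ± 0.11).

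Of 28 immediate early genes 7 rose and 5 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.934), with Nr4a2 at 0.61 ± 0.10 and Zfp36 at -0.60 ± 0.10. After quantile normalization 4 immediate early genes were higher and 5 lower. Of 26 interferon and antigen genes 5 rose and 3 fell (5 and 3; 0.956), with Tapbp at 0.74 ± 0.10, Irf9 at 0.62 ± 0.09 and Oas1a at -0.67 ± 0.13. Of 21 clock genes 4 rose and 4 fell (9 and 6; 0.956), with Nr1d1 at 1.11 ± 0.18, and 1 higher and 5 lower after quantile normalization. Of 25 axon and dendrite genes 9 rose and 2 fell (9 and 2; 0.501), with Stmn3 at 1.23 ± 0.18 and Sema6a at 0.66 ± 0.12. Of 18 pigment epithelium genes 3 rose and 1 fell (3 and 1; 0.956), led by Cst3 with 1.22 ± 0.24, of 27 cytokine and complement genes 3 and 1 (3 and 1; 0.536) with Il18 at 0.62 ± 0.14, and of 19 proliferation genes 3 and 1 (3 and 1; 0.889) with Ube2c at 0.52 ± 0.09 and Pcna at 0.81 ± 0.15. Il18 and Pcna did not pass after quantile normalization (0.0622 and 0.143, ranges 0.0013 to 0.0717 and 0.000459 to 0.143), nor did Il18 without the 3 EGFP arrays lowest in Arr3 (0.0535) or with the cone list mean as a covariate (0.0717). Quantile normalization left Stmn3 at 0.77 and Cst3 at 0.71, the mean of its probes Stmn3 at 0.59 and Pcna at 1.31, and the cone list mean as a covariate Cst3 at 0.58, which passed. None of 6 sex-linked genes (0.956) and 3 red blood cell genes passed. In 11 of 33 lists the median, the mean and the test did not share a sign.

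The large number of calls with eNpHR-EYFP was not matched by other groupings: of 100 splits of the 12 arrays 1, the real one, gave as many calls (9659, highest other 1150). That is the smallest share 100 splits can give, and it argues against a random grouping of the arrays. It shows only that the eNpHR-EYFP and EGFP arrays differ, whatever the cause. Lines left in the wrong place are argued against by the share of calls, 32.9% among moved lines and 32.4% among lines in place (ratio 1.01, probes that name 1 gene). Among probes that name no gene the shares differed, with 26.7% for moved lines and 15.7% for lines in place. The lower share lay in the first block of the table (13.3%), which holds no probe that names 1 gene, while lines in place after it were at 25.7%. A scale difference as the whole cause is argued against by the 76.5% of calls kept after quantile normalization. Fewer other retinal cells beside the cones are argued against as the whole cause by their pooled markers. Of the called markers 92% were higher, and 69.6% after quantile normalization. Among all called probes 66.8% were higher, and 51.5% after quantile normalization, so part of the markers' lean is common to all calls. Bipolar cell genes went the other way after quantile normalization, with 3 higher and 4 lower (median -0.21). For bipolar cells the question therefore stays open. Whether the share of cones accounts for part cannot be told. With the cone list mean as a covariate 60.3% of the calls were kept, but that mean is made of tested genes and itself tended higher on the eNpHR-EYFP arrays. The construct, the number of sorted cells, separate processing and an age course that is not linear cannot be told apart, since 0 eNpHR-EYFP arrays share a cell number or an age with an EGFP array.

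Between 110 and 220 days, where limma called 0 probes and 2331 had an unadjusted p under 0.05, a count of 0 is reached by each of 35 of 35 splits of the 8 EGFP arrays (highest other 1), so that count says nothing about chance. At an unadjusted p under 0.05, 1 of 35 splits, the real one, gave as many probes (2331, highest other 2036). That is the smallest share that 35 splits can give, and the test was chosen after the number was seen. Chance is therefore not excluded, for that number or for any single probe. In simulated data at the usual spread 86% of 2-fold changes were called. There 200 probes were changed, with noise independent between probes, and the adjusted threshold eases as more probes change. Kcng4 (log2 difference 1.51, adjusted p = 0.124 by limma) and Isl1 (1.71, 0.241) differed by over 2-fold and did not pass. Cone genes spread far more widely than most. The simulation therefore cannot exclude too little power for 2-fold changes. Power for smaller changes was not simulated, and an effect of age itself stays open.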
